A study of Zea mays with 4 samples.

How the data were processed

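RNA from 4 maize kernel samples, 2 bt2 mutant (bt2-H2328 allele) and 2 wild type, was measured on 1-colour Affymetrix maize arrays, 1 array per sample. Per the labels, kernels were taken 35 days after pollination from greenhouse plants, 20 µg of total RNA was used except for mutant 2 with 17 µg, and the RNA was amplified and labelled with biotin. The deposited values are log2 values per probe set, made with GCRMA per the submitters' processing notes, a method that corrects background by probe sequence, normalizes between arrays and summarises the probes of a probe set. The log base was read from the deposited values, which run from 1.31 to 15.44 with 2 decimals. The GCRMA version and scanner settings are not given in the sources used here. Whether the arrays were normalized together is not given in the sources used here; where they were, a change of the whole messenger content would not show in these values.

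The table held 17734 probe sets, of which 113 were array controls and 1 had no values. Gene names came from the platform annotation, which is old, updated through Entrez identifiers with a RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0. Of the maize probe sets, 1452 had 1 gene, 1 had several and 16168 had none in that annotation. RefSeq identifiers matched 1377 of the probe sets with 1 gene, for 1060 of 1108 genes, and 973 genes had a name other than a locus number. No coordinates are given, since the files name no genome build.

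Probe sets were kept where at least 2 of the 4 arrays had a log2 value of 4 or more, which left 10458 and removed 7162. Mutant and wild type were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. SE is the moderated standard error of the log2 difference, and n is 2 arrays per group throughout. Where every array of a group lay under a log2 value of 4, the fold is given as a bound against that value. A gene with several probe sets was represented by the one with the highest mean over the 4 arrays. On data simulated on the 10458 probe sets with 200 changed in each of 10 draws, the fit recovered 55.4% of 2-fold and 98.5% of 4-fold changes, and 5.18% of its calls were false. The simulated noise was normal, independent between probe sets and equal in both groups. These rates do not carry over to the real arrays, where 4514 probe sets passed.

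Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, on 1 probe set per gene and with at least 3 measured genes. The lists were written before the data were examined, as symbols and product names. The annotation holds no product names, so membership rested on symbols and synonyms, and some lists became short or caught homonyms. A completed version of the lists was therefore written from gene names alone, before any test was run or any named gene was looked up, and is named as completed wherever it is used. The genes named in the text followed a rule fixed before the data were examined, namely bt2, the 12 largest rises and 12 largest falls among named genes past the threshold whose groups did not overlap, and up to 4 members per list by smallest p. Up to 4 members of each completed list by smallest p, and a few further list members, were named after the annotation or their values were seen.

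Alternatives planned beforehand changed the filter, the normalization, the variance model, array weights, a pseudocount of 16 on the linear scale, the replicate number as a block, the threshold and each array left out in turn. Centring on control probe sets was added after seeing the values, and the completed lists after seeing the annotation, before any test. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The number of arrays limits the precision of every value, and since the labels do not say that the samples came from separate plants, p-values measure the spread between these samples, which may be technical.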

Results

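Transcript levels were measured on arrays in maize kernels, 2 samples of the bt2 mutant (allele bt2-H2328) and 2 of the wild type, all at 35 days after pollination. Bt2 encodes a small subunit of ADP-glucose pyrophosphorylase, the enzyme that makes the sugar nucleotide from which starch is built. The comparison addresses whether other pathways that can use sucrose are induced when starch synthesis is blocked. Values are GCRMA expression values on the log2 scale, and 57.5% to 58.6% of the maize probe sets had a value of 4 or more on each array.

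Mutant and wild-type kernels differed widely. Of 10458 probe sets, 4514 passed the limma test at an adjusted p of 0.05, with 2199 higher and 2315 lower in the mutant, and 2468 of them differed at least 2-fold. Among 781 genes counted by 1 probe set each, 163 rose and 230 fell. The counts of the gene lists below are to be read against these shares. Arrays of 1 group correlated at r = 0.980 for the mutant and 0.986 for the wild type across probe sets, and arrays of different groups at 0.864 to 0.910, where probe sets are not independent replicates. The groups did not overlap in 78.5% of probe sets, against 33.3% by chance.

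These differences are relative to the array-wide scale. Poly-A control RNAs, which are not maize transcripts, were 1.20 higher on the mutant arrays, and centring on them moved every difference by -1.23. That scaling gave 304 higher and 8232 lower calls. It also changed the spread used in the fit, and the limma adjusted p of bt2 was 1.65e-12 there. Both scalings rest on the same arrays, so these calls are not more certain than the main ones. Without mutant 1, mutant 2 or wild type 2, no probe set passed the limma test, although 4523, 4617 and 3633 had an unadjusted p under 0.05. Without wild type 1, 1195 passed.

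bt2 itself fell. Its 1 probe set (gene LOC541902) read 10.13 and 10.12 in the mutants and 12.67 and 12.64 in the wild types, a difference of -2.53 (SE 0.09, n = 2 per group), or 5.78-fold lower, with a limma adjusted p of 0.00514. The adjusted p was 0.0733, 0.0730 and 0.0805 without mutant 1, mutant 2 and wild type 2, at differences of -2.54, -2.53 and -2.55.

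Starch genes fell more often than they rose. Of 5 ADP-glucose pyrophosphorylase subunit genes, 3 fell and 2 did not pass; besides bt2, the large subunit gene sh2 fell by 1.18 and agpsl1 fell by 1.83 on the log2 scale, while AGP2 read 0.84 and did not pass. Adjusted over the list alone, 1 rose and 3 fell, with a camera adjusted p of 0.371. The completed list adds AGPLS3, at 1.14 and not past the threshold, so that 3 of 6 fell and 3 did not pass, or 2 rose and 3 fell adjusted over the list alone. Its median was -0.65 against -1.18 in the fixed list, and its camera adjusted p was 0.611. A second probe set of sh2 differed by -3.18. In the completed list of starch synthesis after ADP-glucose, 6 of 10 genes fell, 1 rose and 3 did not pass, with a camera adjusted p of 0.296. The falls included SBEIIb, a starch branching enzyme, at -1.18 (-0.65 and not past in another probe set), the plastid ADP-glucose carrier bt1 at -1.24, and the debranching enzyme zpu1 at -1.06. The starch synthase ss1 rose by 0.94, and turned to -0.30 when centred on the poly-A controls. The granule-bound starch synthase wx1 read 0.18 and did not pass, against -1.05 and past the threshold on the poly-A scaling. The starch list fixed beforehand gave 6 falls and 1 rise among 9 genes, but 1 of those falls was sus1, a sucrose synthase caught through a shared synonym. Adjusted over the list alone, 6 fell and 1 rose in that fixed list, and its camera adjusted p was 0.313.

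Genes of sucrose use moved both ways. The cell wall invertase incw1, which splits sucrose outside the cell, rose by 4.26 (SE 0.19), 19.2-fold, with a limma adjusted p of 0.00528. The sucrose synthase sus1 fell by 2.40 and the fructokinase frk2 fell by 1.03, while sh1, the main endosperm sucrose synthase, read -0.32 and did not pass, while its second probe set passed at -2.77. Of 7 genes for sucrose cleavage and hexose phosphate entry, 2 rose, 2 fell and 3 did not pass, the same numbers as when adjusted over the list alone, with a camera adjusted p of 0.777. The other rise was phi1 at 0.50, which became -0.73 on the poly-A scaling. SPS, a sucrose phosphate synthase, fell by 3.77 and spp1, a sucrose phosphatase, fell by 0.57.

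Glycolytic genes were lower more often than higher. In the fixed list, 5 of 7 genes fell, 1 rose and 1 did not pass, also when adjusted over the list alone, with a camera adjusted p of 0.313, and in the completed list 7 of 10 fell, 1 rose and 2 did not pass, with 0.152. The cytosolic glyceraldehyde phosphate dehydrogenase genes GAPC3 and gpc4 fell by 2.07 and 0.82, and the enolase genes eno1 and eno2 fell by 0.55 and 0.59. The completed list also counts the pyruvate phosphate dikinase ppdk1, at -2.16, which the fixed amino acid list counts too. Among 5 fermentation genes, the pyruvate decarboxylase pdc2 rose by 1.49, the alcohol dehydrogenase adh2 fell by 1.73 and 3 did not pass, with a camera adjusted p of 0.801. Adjusted over the list alone, again 1 rose and 1 fell. In the completed list of malate, PEP carboxylase and pyruvate dehydrogenase genes, 3 of 7 rose, 1 fell and 3 did not pass, with a camera adjusted p of 0.298. The malate dehydrogenase mdh4 fell by 1.00, and the rises, mdh6, ME1 and pep4, read -0.25, -0.05 and -0.05 on the poly-A scaling.

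Most measured zein genes fell. In the completed list of zeins, the main kernel storage proteins, 5 of 7 genes fell and 2 did not pass, with a median difference of -2.01. z1D_2 fell by 4.93 (SE 0.56), 30.5-fold, and fl2, an alpha zein, fell by 3.68 (SE 0.10), 12.8-fold, while the gamma zein gene zp27 read -0.33 and did not pass, and -0.38 in a second probe set that passed. This was the only completed list past the camera threshold, with an adjusted p of 0.0416, and it did not pass with an estimated correlation (adjusted p 0.790), with the replicate block (0.0527) or without wild type 1 (0.0548). Only fl2 and zp27 were in the list as fixed beforehand, too few for a test. Zein genes are near-identical copies, so a probe set can read several of them. The transcription factor genes pbf1 and o2, known activators of zein genes, fell by 2.70 and 1.05, with o2 at -1.19 and not past in another probe set. In the fixed list of endosperm transcription factors, 3 of 6 genes fell, 2 rose and 1 did not pass, also when adjusted over the list alone, with a camera adjusted p of 0.777. The rises were ohp1 at 0.70, which was -0.54 on the poly-A scaling, and GBF1 at 0.65, which was -0.58 there.

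Some genes for protein folding in the endoplasmic reticulum, where zeins are deposited, fell too, though neither list passed camera. All 4 measured genes of the fixed list fell, also when adjusted over the list alone, with a camera adjusted p of 0.0925. The chaperone genes bip1 and bip2 fell by 2.03 and 1.29 and the calreticulin gene crt2 fell by 1.53. In the completed list 9 of 19 genes fell, 1 rose and 9 did not pass, with a camera adjusted p of 0.152. The protein disulfide isomerase PDIL1-1 fell by 1.70 and PDIL2-1 rose by 1.10, which was -0.14 on the poly-A scaling. Among globulins and other storage proteins, glb3 fell by 1.10 and leg1 fell by 0.64, while the embryo globulins glb1 and glb2 read 0.32 and 0.15 and did not pass. The rise in that fixed list of 5 genes was Hb, a haemoglobin caught through a shared synonym, and adjusted over the list alone 2 rose and 2 fell, with a camera adjusted p of 0.777.

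The largest rises were in genes of varied function. opr1, an oxophytodienoate reductase, rose by 4.82 (SE 0.34), 28.1-fold, with a limma adjusted p of 0.00682. saf1, a safener-induced gene, was at least 17.4-fold higher and aox3, an alternative oxidase of mitochondria, at least 13.6-fold higher, both against wild-type values under 4. mrpa1, an ABC transporter, rose by 4.15, the cytokinin glucosyltransferase czog1 rose by 3.53, the alkaline alpha-galactosidase AGA2 rose by 3.37 and the serine acetyltransferase sat1 rose by 3.18. The chitinase chn1 rose by 3.55 (SE 0.73) and por rose by 3.65 (SE 0.77), both with a wide spread between wild types. psah1, a photosystem I subunit, and ts2 were at least 4.56-fold and 5.74-fold higher. They were ranked by log2 difference against wild-type values under 4, and these bounds do not secure that rank.

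The largest falls included genes of cell expansion and of the transfer cells at the kernel base. bx6, of benzoxazinoid synthesis, was at least 21.3-fold lower in the mutant, the expansin genes expa1 and expB6 at least 17.0-fold and 13.1-fold lower, and gst12, a glutathione S-transferase, at least 13.4-fold lower. nfd101 fell by 3.74 and the GRAS family gene Scl1 fell by 3.62. In the fixed list of markers of the basal endosperm transfer layer, which takes up sugars from the mother plant, 5 of 6 genes fell and 1 rose, also when adjusted over the list alone, with a camera adjusted p of 0.313. betl3, meg2 and betl1c were at least 12.7-fold, 4.82-fold and 5.76-fold lower and betl4 fell by 2.21. The 1 rise was mrpa1, which shares a synonym with the transfer cell regulator but is a transporter. The remaining fall of the fixed list was smaller than that of betl4. The completed list holds neither mrpa1 nor the gene of that remaining fall. In the completed list, 4 of 5 genes fell and 1 did not pass, with a camera adjusted p of 0.0830. Wild type 2 exceeded wild type 1 by 1.63 in betl1c, 1.3 in meg2, 0.94 in betl3 and 0.24 in betl4.

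**Figure D1:**
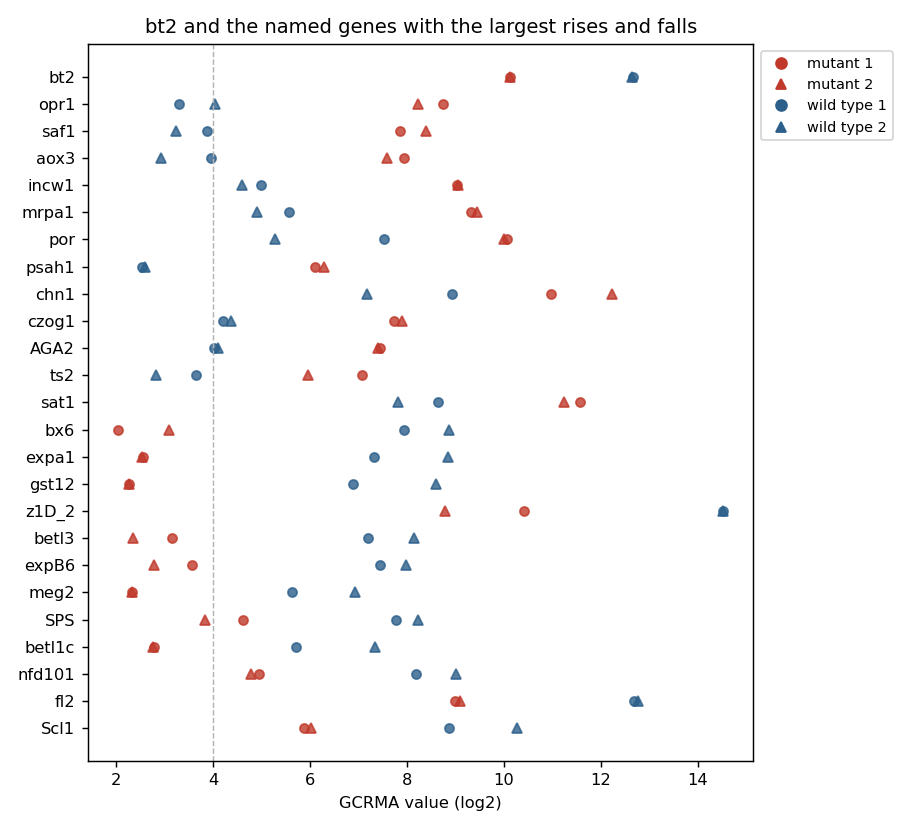
GCRMA expression values on the log2 scale (horizontal axis) of bt2 and the named genes with the largest rises and falls, with 1 point per array, red for mutant and blue for wild type, circles for replicate 1 and triangles for replicate 2, and a dashed line at 4. The mutant values of bt2 are 10.13 and 10.12 against 12.67 and 12.64. The other genes were chosen among those whose groups do not overlap.

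Cell wall genes fell in part. In the fixed list, 3 of 4 genes fell and 1 did not pass, also when adjusted over the list alone, with a camera adjusted p of 0.288. Besides expa1, the cellulose synthase genes CesA-2 and CesA-3 fell by 1.72 and 0.50. In the completed lists, 5 of 7 expansin genes fell, 6 of 12 cellulose synthase and brittle stalk genes fell and 8 of 12 tubulin genes fell, with no rise in any of them. Their camera adjusted p values were 0.0830, 0.115 and 0.0552.

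Several genes of amino acid and phenylpropanoid metabolism rose. In the fixed amino acid list, 5 of 10 genes rose, 3 fell and 2 did not pass, or 5 and 5 adjusted over the list alone, with a camera adjusted p of 0.773 and a list median of 0.30 that was -0.94 on the poly-A scaling. The tryptophan synthase genes TSB1 and TSB2 rose by 2.16 and 2.21 and the asparagine synthetase asn1 rose by 1.99. Among the falls, nac4 at -0.73 is a transcription factor gene caught through a shared synonym, while the glutamine synthetase gln2 fell by 1.36 and the pyruvate phosphate dikinase ppdk1 fell by 2.16. Of 16 genes in the completed list, 7 rose, 3 fell and 6 did not pass, with a camera adjusted p of 0.447. Adjusted over the completed list alone, 7 rose and 6 fell, and its median was -0.0175. In the fixed phenylpropanoid list, all 4 genes rose, also when adjusted over the list alone, with a camera adjusted p of 0.0919. PAL1, which opens the pathway, rose by 2.25 (SE 0.47), while a2 and BM1, at 1.20 and 0.93, turned to -0.04 and -0.30 on the poly-A scaling. The remaining member, an2, at 1.5, is a diterpene synthase gene caught through its symbol. In the completed list, without it, 3 of 5 genes rose and 2 did not pass, with a camera adjusted p of 0.0830 and a median of 1.20 that was -0.035 on the poly-A scaling. In the inositol list 1 of 4 genes fell, also when adjusted over the list alone, and 3 did not pass, with a camera adjusted p of 0.777. That gene was INO1, an inositol phosphate synthase, which fell by 2.31.

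Some late embryogenesis genes rose on the array-wide scale, though neither list passed camera in the main test. With all probe sets of its genes, where dhn2 counts several times, the fixed list had a camera adjusted p of 0.00986. All 3 genes of the fixed list, dhn2, rab17 and EMB5, rose by 2.09, 0.41 and 0.43, also when adjusted over the list alone, with a camera adjusted p of 0.0925, but rab17 and EMB5 read -0.82 and -0.80 on the poly-A scaling. Of 5 genes in the completed list, 4 rose and asr1, at -0.23 and 0.83 in its probe sets, did not pass, with a camera adjusted p of 0.0830. Among 9 embryo markers, 4 rose, 1 fell and 4 did not pass, or 5 and 1 adjusted over the list alone, with a camera adjusted p of 0.0925 and a list median of 0.32 that was -0.91 on the poly-A scaling. Hb is 1 of the 4 rises, again through its synonym. rab17 and EMB5, counted above among the late embryogenesis genes, are also among these rises, so the lists are not separate results. Of 8 in the completed list, 3 rose, 1 fell and 4 did not pass, with a camera adjusted p of 0.152. Of 4 aleurone markers, dek1 rose by 1.64, Nkd1 fell by 1.02 and 2 did not pass, with a camera adjusted p of 0.777. Of 5 pericarp and maternal tissue markers, bde1 and zag2 fell by 1.07 and 1.46 and 3 did not pass, with a camera adjusted p of 0.701. Adjusted over the list alone, these last lists gave the same numbers, 1 rise and 1 fall for the aleurone and 2 falls for the pericarp.

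**Figure D2:**
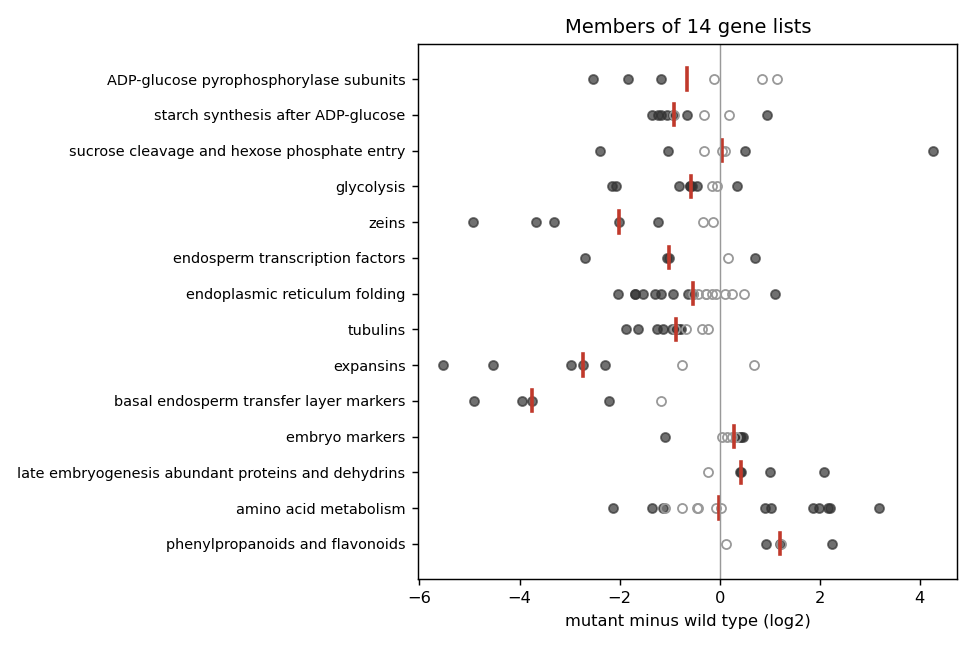
Differences between mutant and wild type on the log2 scale (horizontal axis) for the members of completed gene lists, with filled points past the limma threshold, open points not past it and a red bar at each list's median. The median of the zeins lies at -2.01 and that of the embryo markers at 0.29, the latter at -0.95 when centred on the poly-A controls.

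Stress and redox genes gave mixed counts. Of 9 heat shock genes, 2 rose, 3 fell and 4 did not pass, with hsp18a at 0.73, which was -0.50 on the poly-A scaling, and hsp101 at -0.85. Of 8 redox and detoxification genes, 1 rose, 2 fell and 5 did not pass, with cat2 at -1.01. The rise was cat1 at 0.96, which was -0.28 on the poly-A scaling and read -0.60 in another probe set. Of 3 defence genes, chn1 rose, prp2 fell by 1.38 and Zlp did not pass. The camera adjusted p was 0.777 for each of these 3 lists, and the counts adjusted over the list alone were the same numbers. Among completed lists, heat shock genes gave 2 rises and 3 falls of 10, endosperm transcription factors 1 and 3 of 5, and globulins no rise and 2 falls of 4. Their camera adjusted p values were 0.654, 0.529 and 0.903. With an estimated correlation, every completed list had an adjusted p of at least 0.790. Across the 20 fixed lists tested with limma's camera, none passed an adjusted p of 0.05 and 4 had an unadjusted p under 0.05, while fry, which asks only whether a list's genes move 1 way, passed 7.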

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

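The tests in this part were all chosen after the control probe sets had been seen. The array's control probe sets entered no comparison, and both results come from them.

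The poly-A controls, bacterial RNAs of the kind added to total RNA before labelling, were higher on the mutant arrays by a median of 1.20 in log2 (SD 0.32 over 36 probe sets), in 36 of 36. These probe sets read only dap, lys, phe and thr, with medians of 1.035, 1.675, 1.26 and 1.205. Their SD and count therefore do not measure the spread between samples. The hybridisation controls, of the kind added after labelling, differed by 0.14 (SD 0.11), which argues against brighter hybridisation or scanning. The smaller RNA amount of mutant 2 is argued against by mutant 1, which had as much RNA as the wild types and lay 1.22 above them. A smaller polyadenylated share of the mutant RNA, which need not be biological, and more control RNA added to it cannot be told apart, since the same difference of 1.20 would follow from either. These readings are not the only ones, and broken maize RNA, left open below, was not tested for this difference. Which scaling is right decides the sign of small rises such as that of ss1.

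In maize control genes with probe sets at both ends, the 5′ value relative to the 3′ value was lower on the mutant arrays by a median of -0.51 in log2, in 5 of 6 pairs, but with an SD of 0.64. Gapdh gave -1.55 and actin 0.02, while ef1a entered more than once, at -0.26 and -1.42, with the same 3′ value. Shorter copies made in labelling would lower the poly-A controls alike, and these differed by 0.30 (SD 0.45) over 12 pairs, the other way. The pairs ran from -0.29 for thr to 1.35 for lys, with 2 lower, and repeat designs for the same few RNAs. Since these RNAs were themselves 1.20 higher on the mutant arrays, an effect of signal level is possible and was not tested. Shorter copies are therefore not excluded. Broken maize RNA in the mutant samples may give -0.51, but it cannot be told apart from real changes of the gene family members that these probe sets share.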

How the results depend on the processing

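Counts kept within 1.5 times of the main count under the mean filter, the stricter filter for all 3 counts, quantile normalization, median centring, no trend, robust variance, array weights, the pseudocount and an adjusted p of 0.1. Without a filter 3484 probe sets were higher. By construction fewer passed with 1 probe set per gene (408, with 166 higher and 242 lower), with a 2-fold minimum (2468, with 1132 and 1336) and at an adjusted p of 0.01 (1134, with 533 and 601). Centring on the poly-A controls, chosen after seeing the data, gave 8536 calls, 304 higher and 8232 lower. It moved every difference by -1.23 and also changed the spread used in the fit, with bt2 at a limma adjusted p of 1.65e-12. Centring on the hybridisation controls gave 2877 calls, 1462 higher and 1415 lower, with bt2 at 5.50e-12. These p-values rest on the same arrays and are not more certain than the main ones. The poly-A centring subtracts 1 value per array, so its shift of -1.23 turns calls from higher to lower by construction. An error in that value is shared by all probe sets, so these calls are not separate findings. How far the changed spread altered the counts on either control was not tested. Leaving out 1 array, with fewer samples and a lone array assumed to vary like the other group, gave 0 to 1195 calls, 0 to 599 higher and 0 to 596 lower, and bt2 at -2.55 to -2.52. With the replicate number as a block 3444 passed (1620 higher, 1824 lower) and bt2 stayed at -2.53 with a limma adjusted p of 0.0293; same-numbered arrays deviated together at r = 0.0213 only, so the numbers are not taken to pair the samples. bt2 kept its direction and its side of the threshold under every alternative except those without mutant 1, mutant 2 or wild type 2. Correlations between groups averaged 0.965 without a filter and 0.848 with the stricter one.

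Of the fixed lists, 7 passed with fry, 2 with all probe sets, 1 with quantile normalization, 1 with the poly-A centring and 0 with an estimated correlation, the block or any array left out. Of the completed lists, 1 passed in the main test, 0 with an estimated correlation, 0 with the block, 11 with fry, 6 with all probe sets, 4 with quantile normalization, 4 with the poly-A centring and 1 to 5 with an array left out, the zeins not among the 3 without wild type 1; the cause was not tested. Among 182 genes, namely those of the naming rule, up to 4 per completed list by smallest p and others the text names, these, past the threshold on either scaling, took the other sign under the poly-A centring alone, by its shift, though lpa3 read 0.00 before and had none: ss1 -0.30, phi1 -0.73, pdc3 -1.08, mdh6 -0.25, pdh2 -0.78, glb1 -0.91, ohp1 -0.54, ole16 -0.98, a2 -0.035, BM1 -0.30, MRP4 -1.01, lpa3 -1.23, rab17 -0.82, EMB5 -0.80, TIP1-1 -0.53, hsp18a -0.50, Zlp -0.80, cat1 -0.28, sod3 -1.06, ccp1 -0.86, vp1 -0.77, arf1 -1.12, Sal1 -0.88, ME1 -0.05, pep4 -0.05, glb2 -1.09, FAD8 -1.10, a4Lea -0.22, see2a -0.26, Cystatin-1 -0.13, aos1 -0.42, gst5 -0.24, gsh1 -0.54, pds1 -1.09, vp9 -1.04, eif7 -0.15, eif6 -0.65, hon101 -0.77, wx1 -1.05, PIP1-5 -0.47, GBF1 -0.58, PDIL2-1 -0.14. AGP2 and AGPLS3, past it on neither, read -0.39 and -0.095. Low signal limits genes under a log2 value of 4 on every array of a group, for which folds are given as bounds.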

Other observations

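Some members of further completed lists, chosen after the annotation was seen, passed the limma threshold, while none of these lists passed camera. Among 7 genes of DNA replication and the cell cycle, 4 fell, none rose and 3 did not pass, with pcna2, a replication clamp, at -2.66 and the cyclin gene cycD2 at -1.26. Of 7 histone and high mobility group genes, 3 fell, 1 rose and 3 did not pass, with his1 at -3.28 and his1a at -1.77, while hon101, the rise, was 0.47, or -0.77 on the poly-A scaling. Of 19 ribosomal protein genes, 6 fell, led by rpl29 at -2.28, and 13 did not pass. That is near the share over all genes, where 230 of 781 fell, and adjusted over the list alone 4 fell. Of 14 glutathione S-transferase genes, 5 fell and 2 rose, with gst10 at -2.18 and gst23 at 1.99. The camera adjusted p was 0.376, 0.559, 0.232 and 0.654 for these lists.

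Among 7 oxylipin genes, 3 rose and none fell, with the lipoxygenase lox3 at 1.74 beside opr1, and a camera adjusted p of 0.232; aos1, at 0.81, was -0.42 when centred on the poly-A controls. Among inositol phosphate and galactosidase genes, phytase1, of phytate breakdown, was at least 2.93-fold lower in the mutant, and AGA3b rose by 1.38, with a camera adjusted p of 0.688 for the list. Among water channels, 5 of 19 genes fell and 2 rose, with PIP2-1 at -1.56 and PIP1-5 at 0.77, which was -0.47 on the poly-A scaling, and a camera adjusted p of 0.648. Among probe sets without a gene name and past the threshold, ranked by log2 difference, the largest rise was at least 28.1-fold and the largest fall 70.8-fold. Those next in rank are known only as bounds, so the order is not certain.

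The wild types differed along the same genes that part mutant and wild type, seen and tested on the same data. Across 10458 probe sets, which are not independent, wild type 2 minus wild type 1 correlated with wild type minus mutant at r = 0.544, where 100 simulations with equal spread gave -0.0392 to 0.0340, and the mutants gave -0.0472. After quantile normalization r was 0.549. Both wild types already had a median of 7.96 over the kept probe sets, so that step could change little. It speaks only to differences in the distribution of values between the arrays. Other effects of normalization were not tested, and the simulations drew noise independently for each probe set. Since wild type 2 enters both differences, unequal spread between the arrays could also shift r, and this was not tested. Broken RNA in wild type 1 stays open: from wild type 1 to wild type 2 the 5′ to 3′ difference moved by -0.29 in maize controls and -0.40 in poly-A controls, 0.11 apart with an SD of 0.46. Kernels of different maturity may also give the r of 0.544, but no label gives the maturity of a sample, so this stays open too.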
